A study of Homo sapiens with 9 samples.

How the data were processed

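PolyA RNA of GIST-T1, a human cell line from a gastrointestinal stromal tumour (GIST), was sequenced in 9 libraries. Per the labels, 3 libraries carried an sgRNA against ETV1, 3 an sgRNA against HAND1 and 3 a control sgRNA against Luciferase. RNA was isolated with an RNeasy Plus kit and libraries were made with the NEBNext Ultra II non-stranded kit for the NovaSeq6000, per the labels' protocols. A non-stranded library cannot tell a gene from an overlapping or antisense gene, so the values of such genes are uncertain. STAR, Cufflinks and the hg19 build are named, without versions, per the submitters' processing notes. The annotation, the filters and the way Cufflinks scaled the libraries to each other are not given in the sources used here.

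The values deposited by the authors are FPKM (fragments scaled to transcript length and to the mapped fragments of the library), with 1 value per gene symbol and library. They are not counts, and no count model was applied. The table held 23610 genes, of which 6473 were at 0 in every library (values below 1e-06 were read as 0). In 28 entries a spreadsheet date stood in place of the symbol; 17 of these were tested and none was named. The sgRNA sequences and their positions are not in the labels, and effects of an sgRNA away from its target were not examined. Where an sgRNA acts through small insertions and deletions, the transcript level of its target is a limited check of the labels.

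Genes with a mean of at least 1 FPKM over all 9 libraries were tested, 11348 in all. The values were put on the scale log2(FPKM + 1), with a pseudocount of 1, and fitted with limma 3.58.1 in R 4.3.3, with the group as the only term, all 9 libraries in the fit and an intensity trend in the empirical Bayes step. The fit had 6 residual and 4.15 prior degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene with an adjusted p under 0.05 was called changed. All fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values. The 3 comparisons were ETV1 sgRNA against Luciferase sgRNA, HAND1 sgRNA against Luciferase sgRNA, and HAND1 sgRNA against ETV1 sgRNA.

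Before the data were examined, 27 gene lists were fixed. They held core transcription factors of GIST and gut mesenchyme, markers of interstitial cells of Cajal and GIST, MAPK (ERK) output genes, receptor tyrosine kinases and their ligands, HOX genes, S phase genes, G2 and mitosis genes, p53 targets, BCL2 family genes, interferon response genes, MHC class I genes, cholesterol biosynthesis genes, amino acid and ATF4 stress genes, endoplasmic reticulum chaperones, hypoxia and glycolysis genes, smooth muscle contractile genes, collagens and extracellular matrix genes, TGF-beta and YAP response genes, Hedgehog, WNT and BMP signalling genes, cytokine and NF-kB response genes, ribosome biogenesis genes, ribosomal proteins, oxidative phosphorylation genes, histones, and markers of neuronal and glial, epithelial, and blood and endothelial cells. Lists with at least 5 tested members, 25 in all, were tested with camera from limma at a preset correlation of 0.01, adjusted over the lists of a comparison. The correlation was also estimated from the data, and with an estimate camera also uses fewer degrees of freedom. A call lost with the estimate is thus by itself no sign of a higher correlation. As an alternative fry was run, a rotation test of whether a list moves on balance one way.

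The named genes follow a rule set before the data were examined. It takes ETV1 and HAND1, the 10 called genes with the largest rise and the 10 with the largest fall against Luciferase sgRNA whose 3 values all lay on one side of the 3 control values, and the 6 in each direction between the sgRNAs of ETV1 and HAND1. It also takes from each list up to 4 called members with the smallest adjusted p, or up to 2 members where none was called. Genes named outside this rule are said to be so, and a gene taken in 1 comparison, such as KIT, may be named in the others. Not every gene that the rule takes is named, and some are not reported here.

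No read counts are given, so the depth is unknown in absolute terms. In Cufflinks estimates of low genes, the ratio between libraries clusters at the ratio of what 1 read is worth. From genes between 0.001 and 0.1 FPKM, the most frequent log2 ratio (within 0.01) gave the depth of each library relative to Luciferase sgRNA replicate 1. Ratios taken through HAND1 sgRNA replicate 2 as a second reference differed by at most 0.00118. Transcript lengths came from a reference annotation of another build and were available for 11087 (97.7%) of the genes tested; no coordinates were used.

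Alternatives fixed before the data were examined were a pseudocount of 0.1 or 5, no filter or a minimum of 5 FPKM, median centring over genes of at least 10 FPKM, quantile normalization, no intensity trend, library weights, only the 2 groups compared, the replicate number as a block, each library left out, and a 2-fold threshold. Removal of a length trend from each library, and the estimated correlation without Luciferase sgRNA replicate 3, were chosen after seeing the data. Both comparisons against Luciferase sgRNA share its 3 libraries, so their fold changes and overlap were set beside 100 simulations of unchanged groups, which hold no effects.

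The steps were tested on simulated data of 11348 genes, with 50 genes changed by each of 4 sizes. For ETV1 sgRNA against Luciferase sgRNA, 28% of the genes planted at 1.25-fold, 64% at 1.5-fold, 88% at 2-fold and 98% at 4-fold were recovered, with 8 false calls. For HAND1 sgRNA against Luciferase sgRNA the shares were 52%, 78%, 96% and 100%, with 9 false calls, and between the sgRNAs of HAND1 and ETV1 they were 26%, 72%, 90% and 100%, with 9 false calls. In the fit of the real data a gene has the same SE in all 3 comparisons, so these shares do not rank the comparisons by power. More genes were planted than limma called with ETV1 sgRNA, so the shares may be too high for that comparison. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for the depth estimate and the plots.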

Results

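The transcriptome of GIST-T1 was measured in 9 libraries to ask which transcripts depend on ETV1 and on HAND1. ETV1 is an ETS family transcription factor of interstitial cells of Cajal, the pacemaker cells of the gut, and of GIST. HAND1 is a basic helix-loop-helix transcription factor of mesoderm development. An sgRNA against ETV1, against HAND1 or against Luciferase, a control sequence with no counterpart in human cells, was present in 3 libraries each. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

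The depth of the libraries relative to Luciferase sgRNA replicate 1 ranged from 0.636 (ETV1 sgRNA replicate 2) to 0.952 (HAND1 sgRNA replicate 2). Between 11283 and 11345 genes reached 1 FPKM in a library, and the upper quartile lay between 12.2 and 12.4 FPKM. Luciferase sgRNA replicate 3 stood apart. It had the highest sum of FPKM, and ribosomal protein genes took 9.91% of it, against 7.70% and 8.16% in the other Luciferase sgRNA libraries. Its genes with transcripts under 1000 nt lay 0.38 (log2, median) above the other libraries of its group. Those of Luciferase sgRNA replicates 1 and 2 lay at −0.28 and −0.12, in comparisons that include replicate 3 and so carry part of its deviation. Most markers of other cell types were low: 20 of 21 blood and endothelial markers, 15 of 20 epithelial markers and 23 of 25 neuronal and glial genes had a mean below 1 FPKM. The exceptions included KRT18, a keratin, at a mean of 225 FPKM, and TUBB3, a tubulin, at 58.5 FPKM, while each of the others had a mean of at most 5.05 FPKM (CD68).

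**Figure D1:**
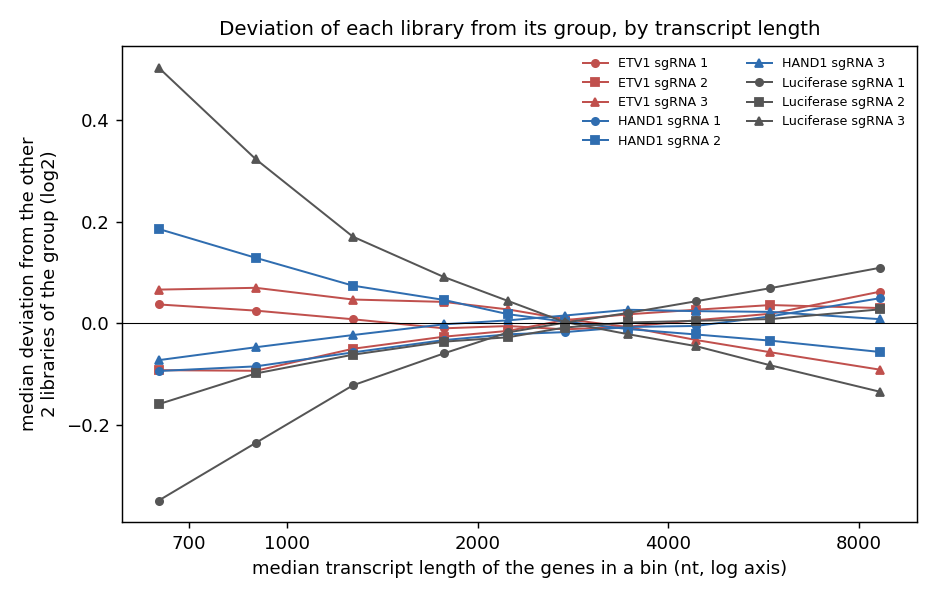
Median deviation (log2) of each of the 9 libraries from the other 2 libraries of its group, over bins of genes ordered by median transcript length (nt, log axis). Luciferase sgRNA replicate 3 lies highest for the shortest genes and Luciferase sgRNA replicate 1 lowest, the latter in a comparison that includes replicate 3.

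Both targeted transcripts were lower in the libraries with their own sgRNA. ETV1 was at 39.7 ± 2.42 FPKM (SD, n = 3) with Luciferase sgRNA, 11.4 ± 0.571 with ETV1 sgRNA and 40.8 ± 0.960 with HAND1 sgRNA. HAND1 was at 114 ± 1.12 FPKM with Luciferase sgRNA, 132 ± 2.26 with ETV1 sgRNA and 38.3 ± 2.25 with HAND1 sgRNA. In limma, ETV1 fell by 1.71 (log2, SE 0.061, adjusted p = 6.22e-07) with its own sgRNA, and HAND1 fell by 1.55 (SE 0.052, adjusted p = 2.07e-07) with its own. The other 2 differences from the control were not called: 0.04 for ETV1 with HAND1 sgRNA (adjusted p = 0.761) and 0.21 for HAND1 with ETV1 sgRNA (adjusted p = 0.244).

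**Figure D2:**
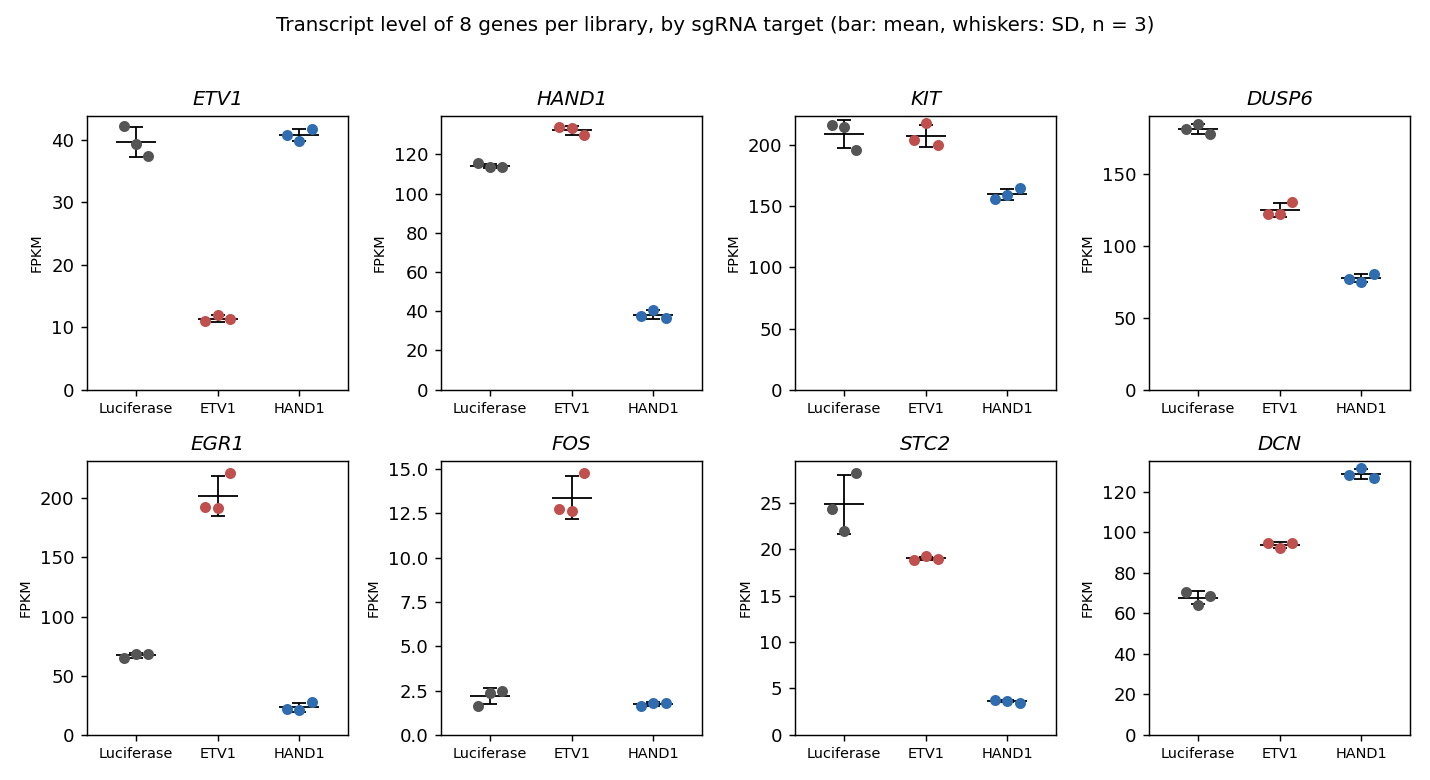
FPKM of 8 genes in each of the 9 libraries, by sgRNA target; points are libraries, bars the mean and whiskers the SD (n = 3). ETV1 and HAND1 were lower with their own sgRNA, EGR1 and FOS were highest with ETV1 sgRNA, and STC2, KIT and DUSP6 were lowest with HAND1 sgRNA.

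With ETV1 sgRNA, the largest rises over Luciferase sgRNA were those of FOS and EGR1, immediate early transcription factors. FOS rose from 2.18 ± 0.460 to 13.4 ± 1.21 FPKM (SD, n = 3; log2 2.19, adjusted p = 2.07e-05) and EGR1 from 67.3 ± 1.94 to 202 ± 16.9 FPKM (log2 1.57, adjusted p = 6.56e-05). IGFBP3, a secreted binder of insulin-like growth factors, rose by 0.84 (log2), COL12A1, a collagen, by 0.66, and ACTA2, smooth muscle actin, by 0.59. Apart from ETV1 itself, the genes that fell most were TRIB1 (log2 −0.76), a pseudokinase, RASL11A (−0.68), a RAS-like protein, and DUSP6 (−0.53), the phosphatase of ERK. KIT, the receptor tyrosine kinase that is mutated in most GIST, was at 207 ± 9.22 FPKM against 209 ± 11.3 (log2 −0.01, adjusted p = 0.982).

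In all, limma called 23 of 11348 genes, 16 higher and 7 lower, and 930 genes had an unadjusted p under 0.05. Besides those above, the called genes that rose were NAB2, a co-repressor of EGR1 (0.63), APOBEC3B, a cytidine deaminase (0.55), MATN2, a matrix protein (0.51), JUN, a partner of FOS (0.48), CD248 (0.47), DCN, the proteoglycan decorin (0.47), and PDGFRA, a receptor tyrosine kinase (0.38). Those that fell were MYCN, a MYC family transcription factor (−0.46), PTGS2, a prostaglandin synthase (−0.43), and SPRY4, a feedback inhibitor of receptor signalling (−0.41). ZFP36L2 (0.46), SPRY1 (0.40), DKK2 (0.38) and TP53I11 (0.38) were also higher and were chosen after their values were seen. The calls of these 4 genes were not followed with a library left out.

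Several of the smaller changes with ETV1 sgRNA lost their call in limma when a library was left out. PDGFRA (adjusted p = 0.0436), kept under 5 of 20 alternatives, lost it without ETV1 sgRNA replicates 1, 2 and 3 (adjusted p = 0.143, 0.228 and 0.150), HAND1 sgRNA replicates 1, 2 and 3 (0.104, 0.0954 and 0.0926) and Luciferase sgRNA replicates 1, 2 and 3 (0.0929, 0.170 and 0.0890). In the same order of libraries MATN2 was at 0.157, 0.202, 0.150, 0.0954, 0.0954, 0.0795, 0.0595, 0.122 and 0.0564, and APOBEC3B at 0.0639, 0.128, 0.135, 0.0757, 0.0571, 0.0696, 0.118, 0.106 and 0.0736. CD248 was lost without any ETV1 sgRNA library (adjusted p = 0.162, 0.192 and 0.0568), HAND1 sgRNA replicates 1 and 2 (0.0757 and 0.0571) and Luciferase sgRNA replicates 1 and 2 (0.152 and 0.170). JUN was lost without ETV1 sgRNA replicates 1 and 3 (0.114 and 0.135), HAND1 sgRNA replicates 1, 2 and 3 (0.0557, 0.0571 and 0.0535) and Luciferase sgRNA replicates 1 and 2 (0.0676 and 0.0955). PTGS2 was lost without each ETV1 sgRNA library (0.0800, 0.0847 and 0.125) and Luciferase sgRNA replicates 1 and 2 (0.0929 and 0.122). NAB2 was lost without ETV1 sgRNA replicates 1 and 3 (0.0723 and 0.0568) and Luciferase sgRNA replicates 1 and 2 (0.0529 and 0.0648), and MYCN without ETV1 sgRNA replicate 1 (0.0639).

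Leaving out a library gave between 11 and 28 called genes for ETV1 sgRNA. The count was 11 without ETV1 sgRNA replicate 1, 14 without ETV1 sgRNA replicate 3, 13 and 14 without Luciferase sgRNA replicates 1 and 2, and 15 without HAND1 sgRNA replicate 1 or 2. Without Luciferase sgRNA replicate 3 it was 28, of which 19 were among the 23.

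Collagens and extracellular matrix genes were higher with ETV1 sgRNA as a list: 2 of 28 rose (COL12A1 and DCN), 0 fell, and 11 were higher adjusted over the list alone (median log2 0.14, camera adjusted p = 3.71e-10). The adjusted p was 0.0145 with an estimated correlation and 0.116 with an estimated correlation and without Luciferase sgRNA replicate 3. Of 17 smooth muscle contractile genes, ACTA2 rose, 0 fell and 5 were higher adjusted over the list alone (median 0.13, adjusted p = 1.60e-04). That list also had an adjusted p of 0.0415 with an estimated correlation and of 0.116 with the estimate and without Luciferase sgRNA replicate 3.

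The 19 MAPK output genes, transcripts that ERK signalling induces, moved in both directions with ETV1 sgRNA. FOS, EGR1 and SPRY1 rose, DUSP6 and SPRY4 fell, and adjusted over the list alone 4 were higher and 2 lower. The list was not called (camera adjusted p = 0.492; median −0.03, mean 0.16, test direction higher). SPRY4 lost its call with quantile normalization (adjusted p = 0.166) and with only the 2 groups in the fit (adjusted p = 0.0545). Of 18 interstitial cell of Cajal and GIST markers DUSP6 fell and 0 rose (2 higher and 1 lower adjusted over the list alone; adjusted p = 0.935). Of 18 receptor tyrosine kinases and ligands PDGFRA rose and 0 fell (1 and 0 adjusted over the list alone; adjusted p = 0.747), and without Luciferase sgRNA replicate 3 limma called 0. Among 20 core transcription factors ETV1 alone was called, with 4 higher and 3 lower adjusted over the list alone (adjusted p = 0.258; median 0.08, mean −0.04, test direction higher). Of 10 cytokine and NF-kB genes PTGS2 fell and 0 rose (1 and 1 adjusted over the list alone; adjusted p = 0.700).

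Several lists without a called member in limma passed camera with ETV1 sgRNA and lost the call with an estimated correlation. Of 26 interferon response genes 0 were called, also adjusted over the list alone, and 5 had an unadjusted p under 0.05 (median 0.12, adjusted p = 0.00129, and adjusted p = 0.0715 with an estimated correlation). TGF-beta and YAP response genes had 0 of 18 called, 3 higher adjusted over the list alone and 4 at an unadjusted p under 0.05 (adjusted p = 0.0190, and 0.172 with an estimated correlation). The call of this list was also lost without ETV1 sgRNA replicate 2 (adjusted p = 0.0676) or 3 (0.114) and without Luciferase sgRNA replicate 1 (0.0506) or 2 (0.0554). Lower lists were amino acid and ATF4 stress genes (0 of 25 called, 1 adjusted over the list alone, 6 at an unadjusted p under 0.05; adjusted p = 0.00158, and 0.200 with an estimated correlation) and cholesterol biosynthesis genes (0 of 24 called, also adjusted over the list alone, 4 unadjusted; adjusted p = 0.00391, and 0.172 with an estimated correlation). Hypoxia and glycolysis genes were lower too (0 of 26 called, 1 higher adjusted over the list alone, 3 unadjusted; adjusted p = 0.0190, and 0.577 with an estimated correlation). Without Luciferase sgRNA replicate 3 the adjusted p was 0.0501 for the cholesterol list and 0.271 for the hypoxia list, and without ETV1 sgRNA replicate 1 it was 0.111 for the hypoxia list.

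Ribosomal protein genes (median −0.09, adjusted p = 0.0176) and nuclear-encoded oxidative phosphorylation genes (median −0.08, adjusted p = 0.00372) were lower with ETV1 sgRNA as lists. In limma 0 of 54 and 0 of 41 members were called, also adjusted over the list alone, with 2 and 1 at an unadjusted p under 0.05. With an estimated correlation both had an adjusted p of 0.826. Both medians depended on Luciferase sgRNA replicate 3, and without that library they were 0.06 (adjusted p = 0.0378) and 0.03 (adjusted p = 0.515), above 0. Without ETV1 sgRNA replicate 2 the adjusted p was 0.211 and 0.1.

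Lists that were not called with ETV1 sgRNA and had 0 called members in limma, also adjusted over the list alone, were HOX genes (25 members, 3 at an unadjusted p under 0.05; camera adjusted p = 0.747), S phase genes (40, 3; 0.747), G2 and mitosis genes (40, 2; 0.492), p53 targets (27, 2; 0.765) and BCL2 family genes (12, 1; 0.492). The same held for endoplasmic reticulum chaperones (22, 1; 0.916), ribosome biogenesis genes (34, 3; 0.105), MHC class I genes (6, 0; 0.410), epithelial markers (5, 1; 0.413) and histones (11, 1; 0.908). The ribosome biogenesis list was called without Luciferase sgRNA replicate 2 (adjusted p = 0.0461). Epithelial markers had a median of −0.02, a mean of 0.13 and a test direction of higher. Of 19 Hedgehog, WNT and BMP signalling genes 0 were called, 2 were higher adjusted over the list alone and 5 had an unadjusted p under 0.05 (adjusted p = 0.700). TUBB3 (log2 0.08, adjusted p = 0.829) and MAP2 (−0.06, adjusted p = 0.953), the neuronal genes measured, and CD68 (0.23, adjusted p = 0.701), the macrophage marker measured, were not called.

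**Figure D3:**
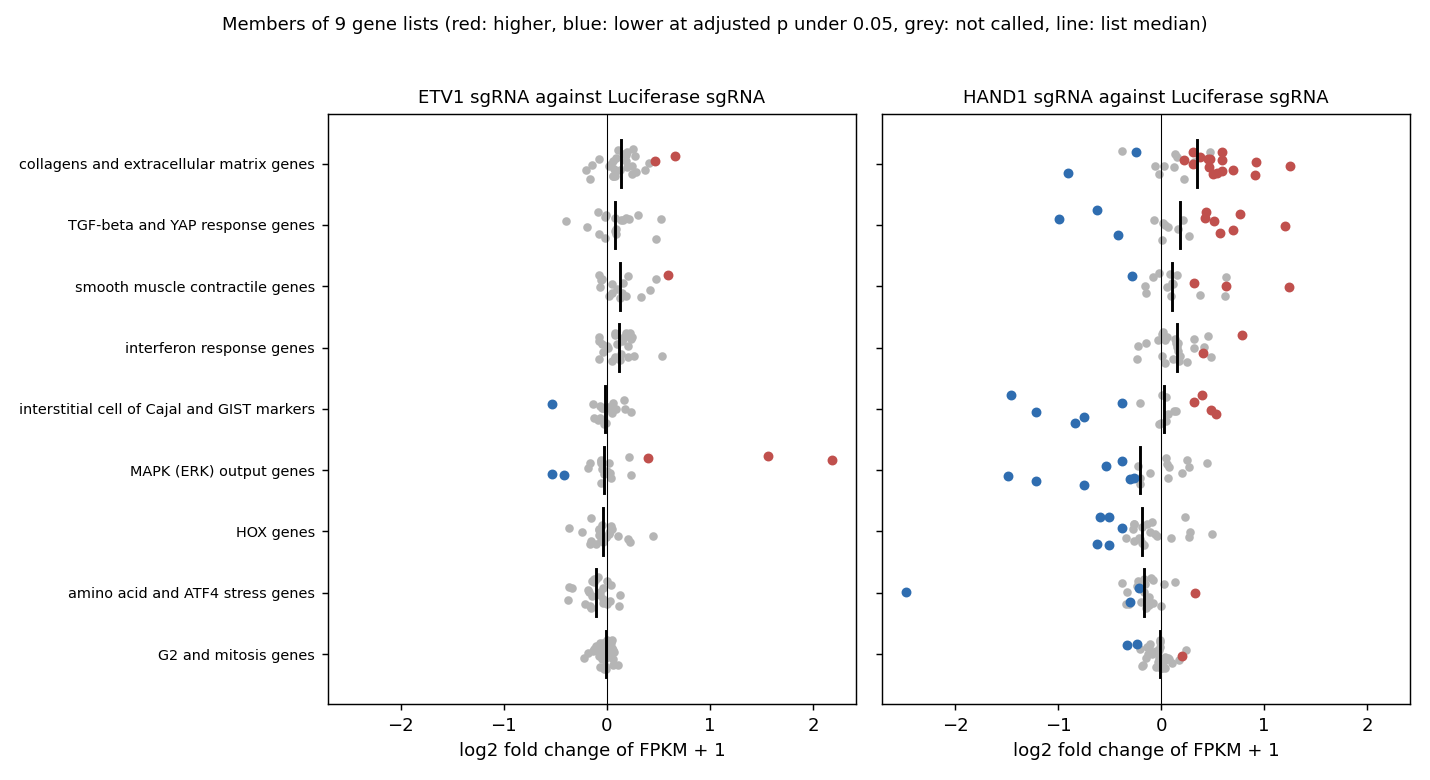
Log2 fold change of FPKM + 1 of each measured member of 9 gene lists, with ETV1 sgRNA (left) and HAND1 sgRNA (right) against Luciferase sgRNA; red and blue points were called higher and lower, grey points were not called, and black lines are list medians. Of 28 extracellular matrix genes 2 rose with ETV1 sgRNA, and 16 rose and 2 fell with HAND1 sgRNA.

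With HAND1 sgRNA, the largest fall was that of STC2, a secreted glycoprotein, from 24.8 ± 3.18 to 3.62 ± 0.123 FPKM (SD, n = 3; log2 −2.47, adjusted p = 2.07e-07). TMEM100, an endothelial and BMP-regulated membrane protein, fell from 231 ± 14.9 to 83.5 ± 3.17 FPKM (−1.45, adjusted p = 7.78e-07), and TBX2, a T-box transcription factor, from 28.0 ± 0.126 to 10.3 ± 1.53 FPKM (−1.37, adjusted p = 2.48e-05). EGR1 fell from 67.3 ± 1.94 to 23.5 ± 3.79 FPKM (−1.49, adjusted p = 1.81e-05). Among the genes that rose most were the ephrin receptor EPHB1 (1.66, adjusted p = 1.98e-04), IGFBP3 (from 1.78 ± 0.0834 to 7.28 ± 0.253 FPKM, 1.57, adjusted p = 6.65e-06) and the WNT antagonist APCDD1 (1.42, adjusted p = 3.91e-04). KIT fell from 209 ± 11.3 to 160 ± 4.51 FPKM (−0.38, adjusted p = 0.00336), a call lost with quantile normalization (−0.28, adjusted p = 0.129).

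In all, limma called 749 of 11348 genes, 417 higher and 332 lower, of which 27 and 21 changed at least 2-fold. Other large falls were those of NPPC, a natriuretic peptide (−1.76), IL12A, a cytokine subunit (−1.37), CGNL1, a junction protein (−1.36), and AFF3, a nuclear protein (−1.34). CTSL1P8, a pseudogene, fell by 1.37, and because it can share reads with CTSL1 (−1.19, named after its value was seen) its value is uncertain. Other large rises were those of VSTM2A (1.40), GPR37, a G protein-coupled receptor (1.37), MYBPH (1.29), the proteases ADAMTS8 (1.29) and MMP1 (1.28), and WNT11, a WNT ligand (adjusted p = 2.21e-04). IPO11-LRRC70, a readthrough of overlapping genes, was at 2.58 ± 0.735 FPKM against 0.519 ± 0.898 (1.37, adjusted p = 0.0293), and its value is uncertain for that reason; the call was lost without any of the HAND1 sgRNA libraries or Luciferase sgRNA replicate 1 or 2 (adjusted p = 0.0833, 0.111, 0.0543, 0.0878 and 0.1).

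Leaving out a library gave between 433 and 729 called genes for HAND1 sgRNA. The counts were 489, 482 and 433 without HAND1 sgRNA replicates 1, 2 and 3, and 488 without Luciferase sgRNA replicate 2. Leaving out Luciferase sgRNA replicate 3 gave 708, of which 584 were among the 749.

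Collagens and extracellular matrix genes rose broadly with HAND1 sgRNA: 16 of 28 rose, 2 fell and 10 were not called, and adjusted over the list alone 20 were higher and 3 lower (median log2 0.35, camera adjusted p = 2.73e-12). DCN rose from 67.7 ± 3.18 to 129 ± 2.58 FPKM (0.92), THBS1, thrombospondin, from 83.3 ± 5.79 to 158 ± 3.79 FPKM (0.91), and TIMP3, a metalloprotease inhibitor, by 0.54. FBN1, the microfibril protein fibrillin, fell from 45.2 ± 4.27 to 23.6 ± 1.33 FPKM (−0.90). The list's adjusted p was 0.00863 with an estimated correlation, and 0.0622 with the estimate and without Luciferase sgRNA replicate 3, where 16 members again rose and 2 fell.

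TGF-beta and YAP response genes were higher with HAND1 sgRNA as a list, with 7 of 18 higher and 3 lower (8 and 3 adjusted over the list alone; adjusted p = 0.00188, and 0.0779 with an estimated correlation). CTGF, a matricellular protein, rose by 1.21 (log2), AMOTL2 by 0.51 and the receptor TGFBR2 by 0.44. BMP4, a secreted ligand, rose from 112 ± 3.48 to 190 ± 3.47 FPKM (0.76). Of 17 smooth muscle contractile genes 3 rose, TAGLN (1.24), CAV1 (0.63) and CNN2 (0.32), and SMTN fell (−0.28). Adjusted over the list alone 4 were higher and 1 lower (adjusted p = 0.00898, and 0.105 with an estimated correlation). The call of SMTN was lost without HAND1 sgRNA replicate 2 (adjusted p = 0.0650) or Luciferase sgRNA replicate 1 (0.0526) or 2 (0.0533), and with quantile normalization (0.103). Interferon response genes had 2 of 26 higher, IFIT1 (0.78) and IFIT5 (0.41), and 0 lower, with the same counts adjusted over the list alone (adjusted p = 0.00188, and 0.0779 with an estimated correlation). IFIT5 was not called without HAND1 sgRNA replicate 2 (adjusted p = 0.0578) or 3 (0.0535).

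MAPK output genes were lower with HAND1 sgRNA: 7 of 19 fell and 0 rose, with 8 lower and 4 higher adjusted over the list alone (median −0.20, adjusted p = 0.00430, and 0.268 with an estimated correlation). DUSP6 fell from 181 ± 3.58 to 77.4 ± 2.66 FPKM (log2 −1.22), SPRY4 from 165 ± 5.07 to 97.9 ± 1.02 FPKM (−0.75) and PHLDA1 by 0.53. Of 18 markers of interstitial cells of Cajal and GIST 5 fell and 4 rose, with 5 and 5 adjusted over the list alone (adjusted p = 0.744; median 0.02, mean −0.15, test direction lower). TMEM100, DUSP6 and the orphan receptor GPR20 (−0.84) fell, and GUCY1A3, a subunit of the nitric oxide receptor guanylate cyclase, rose by 0.53. Among 18 receptor tyrosine kinases and ligands KIT, its ligand KITLG (−0.56) and the growth factor receptor FGFR4 (−0.47, named after its value was seen) fell, and ERBB3 (0.64) and EGFR (0.45) rose (3 higher and 5 lower adjusted over the list alone; adjusted p = 0.744).

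HOX genes, transcription factors of body position, were lower as a list with HAND1 sgRNA: 5 of 25 fell and 0 rose, with 8 lower and 2 higher adjusted over the list alone (median −0.19, adjusted p = 0.00383, and 0.0779 with an estimated correlation). HOXB13 fell by 0.63, HOXB9 by 0.60 and HOXA11 by 0.38. HOXC13 (−0.50) was not called without HAND1 sgRNA replicate 2 (adjusted p = 0.0603) or 3 (0.0749) or Luciferase sgRNA replicate 2 (0.0537). Among 20 core transcription factors HAND1 and TBX2 fell, and PITX1, a homeobox gene of the hindlimb, rose from 349 ± 18.4 to 503 ± 25.5 FPKM (0.52). The list had 3 members higher and 2 lower, 4 and 4 adjusted over the list alone, and was not called by camera (adjusted p = 0.959, median 0.01, mean −0.11, test direction lower). Of 19 Hedgehog, WNT and BMP signalling genes 5 rose and 2 fell, with 6 and 4 adjusted over the list alone (adjusted p = 0.529; mean −0.00177 and median 0.00473, test direction higher). SFRP1, a secreted WNT antagonist, fell from 117 ± 2.71 to 47.1 ± 3.62 FPKM (−1.30), and GLI3, a Hedgehog effector, rose by 0.44.

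Amino acid and ATF4 stress genes were lower with HAND1 sgRNA (3 of 25 lower and 1 higher; 9 and 1 adjusted over the list alone; adjusted p = 1.98e-04, and 0.120 with an estimated correlation). STC2 and ASNS, asparagine synthetase (−0.30), fell, and ATF5 rose (0.33), a call lost without HAND1 sgRNA replicate 3 (adjusted p = 0.0552) or Luciferase sgRNA replicate 2 (0.0519). Ribosome biogenesis genes had 3 of 34 lower and 0 higher, also adjusted over the list alone (adjusted p = 0.00188, and 0.230 with an estimated correlation). HSPD1, a mitochondrial chaperone (−0.25), and NPM1, a nucleolar protein (−0.32), fell, both not called without HAND1 sgRNA replicate 1 (adjusted p = 0.0543 and 0.0782) or 3 (0.0585 and 0.0620), and NPM1 also not without Luciferase sgRNA replicate 2 (0.0654). With quantile normalization HSPD1 was at −0.16 (adjusted p = 0.224) and NPM1 at −0.24 (adjusted p = 0.0671), both not called. In the hypoxia and glycolysis list the called members and the test went opposite ways. EGLN3, an oxygen sensor (0.70), and NDRG1 (0.54) rose and 0 fell, while the list was lower (2 higher and 4 lower adjusted over the list alone; median −0.13, adjusted p = 0.00779, and 0.348 with an estimated correlation and 0.103 with quantile normalization).

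Ribosomal protein genes (median −0.17, adjusted p = 1.98e-04) and oxidative phosphorylation genes (median −0.16, adjusted p = 0.00179) were lower as lists with HAND1 sgRNA too. In limma 0 of 54 and 0 of 41 were called, also adjusted over the list alone, with 7 and 7 at an unadjusted p under 0.05, and both had an adjusted p of 0.673 with an estimated correlation. Both medians again depended on Luciferase sgRNA replicate 3, and without it they were −0.01 (adjusted p = 0.457) and −0.04 (adjusted p = 0.554).

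Other lists were not called by camera with HAND1 sgRNA. Fry called the cytokine and NF-kB list (adjusted p = 0.00128) and cholesterol biosynthesis genes (0.0203) lower. It also called lower the interstitial cell of Cajal and GIST markers (3.95e-04) and the core transcription factors (0.00685), which include HAND1. Of the camera calls, fry kept MAPK (4.25e-04), HOX (0.00128), amino acid (0.00117) and TGF-beta genes (6.03e-04). It also kept extracellular matrix (9.81e-06), smooth muscle (6.59e-04), interferon response (0.00276), ribosome biogenesis (0.00685) and hypoxia and glycolysis genes (0.0394). It did not keep ribosomal protein or oxidative phosphorylation genes (0.302 each). Of 10 cytokine and NF-kB genes 3 fell and 0 rose, with 3 and 1 adjusted over the list alone (adjusted p = 0.0869): TNFAIP3, an inhibitor of NF-kB (−0.94), PTGS2 (−0.75) and the chemokine CCL2 (−0.61). The list was called without HAND1 sgRNA replicate 1 (adjusted p = 0.0421) or 3 (0.0291) or Luciferase sgRNA replicate 2 (0.0432). Among 27 p53 targets PLK2 (0.85), BTG2 (0.30) and GDF15 (0.52) rose and 0 fell, with the same counts adjusted over the list alone (adjusted p = 0.537). GDF15 was not called without HAND1 sgRNA replicate 2 (adjusted p = 0.0559). Cholesterol biosynthesis genes had 1 of 24 higher and 3 lower, also adjusted over the list alone (adjusted p = 0.0761 for the list, and 0.0394 without Luciferase sgRNA replicate 2).

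Proliferation genes moved little with HAND1 sgRNA. The S phase list had 2 of 40 lower and 0 higher, RFC2 (−0.28) and GINS4 (−0.27), and the G2 and mitosis list 2 lower and 1 higher of 40, with the same counts adjusted over each list alone (adjusted p = 0.671 and 0.540). PTTG1, securin, the inhibitor of separase, was at −0.33 and was not called without HAND1 sgRNA replicate 1 (adjusted p = 0.102) or 3 (0.116) or Luciferase sgRNA replicate 2 (0.0643). BMF, a pro-apoptotic protein, rose by 0.48, as the called member among 12 BCL2 family genes, also adjusted over the list alone (adjusted p of the list = 0.671). That call was lost without any HAND1 sgRNA library or Luciferase sgRNA replicate 1 (adjusted p = 0.0695, 0.0545, 0.0703 and 0.0567). In limma 0 members were called, also adjusted over the list alone, among endoplasmic reticulum chaperones (22 measured, 6 at an unadjusted p under 0.05; camera adjusted p = 0.570), MHC class I genes (6, 1; 0.526), epithelial markers (5, 1; 0.959) and histones (11, 1; 0.540). Epithelial markers had a median of −0.00474, a mean of 0.04 and a test direction of higher. Of the markers of other cell types MAP2 rose (0.64, adjusted p = 0.0148) and CD68 from 4.06 ± 0.629 to 6.13 ± 0.692 FPKM (0.50, adjusted p = 0.0466). MAP2 was not called without HAND1 sgRNA replicate 1 or 2 or Luciferase sgRNA replicate 2 (adjusted p = 0.0513, 0.0680 and 0.0588), and CD68 not without any HAND1 sgRNA library, ETV1 sgRNA replicate 1 or Luciferase sgRNA replicate 1 or 3 (adjusted p = 0.0550, 0.151, 0.143, 0.0717, 0.110 and 0.108).

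Set directly against each other, HAND1 sgRNA and ETV1 sgRNA differed most in EGR1, at 23.5 ± 3.79 against 202 ± 16.9 FPKM (SD, n = 3; log2 −3.05, adjusted p = 1.28e-07). FOS (−2.40, adjusted p = 2.80e-06), STC2 (−2.11), IL12A (−1.67) and CGNL1 (−1.52) were also lower with HAND1 sgRNA. EPHB1 (1.74), GPR37 (1.51), WNT11 (adjusted p = 1.63e-04), COL15A1, a basement membrane collagen (1.37), and ABI3BP, a matrix protein (1.19), were higher. ETV1 was higher (1.75, adjusted p = 1.63e-07) and HAND1 lower (−1.76, adjusted p = 9.46e-08) with HAND1 sgRNA. KIT was lower with HAND1 sgRNA than with ETV1 sgRNA (−0.37, adjusted p = 0.00549).

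In this comparison limma called 460 genes, 228 higher and 232 lower with HAND1 sgRNA, of which 13 and 21 differed at least 2-fold. The counts were 295 and 294 without ETV1 sgRNA replicates 1 and 2, and 271, 291 and 272 without HAND1 sgRNA replicates 1, 2 and 3. Without Luciferase sgRNA replicate 3, which enters through the shared spread, there were 592, with 448 of the 460 among them.

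MAPK output genes were lower with HAND1 sgRNA than with ETV1 sgRNA, with 7 of 19 lower and 0 higher (9 and 2 adjusted over the list alone; adjusted p = 5.70e-05, and 0.207 with an estimated correlation). Extracellular matrix genes were higher, with 10 of 28 higher and 3 lower (18 and 5 adjusted over the list alone; adjusted p = 5.70e-05, and 0.0937 with an estimated correlation). HOX genes were lower, with 3 of 25 lower and 0 higher (7 and 0 adjusted over the list alone; adjusted p = 0.00388, and 0.1 with an estimated correlation), and were not called without HAND1 sgRNA replicate 3 (adjusted p = 0.0544). Ribosomal protein genes (adjusted p = 0.0369) and ribosome biogenesis genes (adjusted p = 0.0412) were lower, with 0 of 54 and 0 of 34 called in limma, also adjusted over the list alone, and 1 and 4 at an unadjusted p under 0.05. Those adjusted p were 0.840 and 0.676 with an estimated correlation. Leaving out ETV1 sgRNA replicate 3 (adjusted p = 0.280 and 0.121) or HAND1 sgRNA replicate 3 (0.228 and 0.0827) ended both calls. The ribosomal protein call was also lost without ETV1 sgRNA replicate 1 (0.0541) or HAND1 sgRNA replicate 1 (0.219), and the ribosome biogenesis call without ETV1 sgRNA replicate 2 (0.0818) or HAND1 sgRNA replicate 2 (0.0744). The other 20 lists were not called by camera, among them amino acid and ATF4 stress genes (adjusted p = 0.0662), which were called without ETV1 sgRNA replicate 1 (0.0366). Fry called lower the amino acid and ATF4 stress genes (adjusted p = 0.0230), interstitial cell of Cajal and GIST markers (4.88e-04) and cytokine and NF-kB genes (0.00411). It called TGF-beta and YAP response genes higher (0.00905). Median and mean differed in sign for receptor tyrosine kinases (−0.01 and 0.00946, test direction lower), Hedgehog, WNT and BMP genes (0.03 and −0.02, higher), cytokine and NF-kB genes (0.00702 and −0.17, lower) and histones (−0.10 and 0.03, lower).

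Some genes changed with both sgRNAs against the shared control. CD248, DCN, DKK2, IGFBP3, JUN, MATN2, NAB2 and ZFP36L2 were called higher with both, and DUSP6, MYCN, PTGS2, RASL11A, SPRY4 and TRIB1 lower with both. EGR1 was called in both comparisons in opposite directions. Independent lists of these sizes would share 0.588 higher and 0.205 lower genes, a value that leaves out the shared controls. In 100 simulations of unchanged groups against the same control libraries 0 were shared, a value that leaves out the effects, so neither is a no-change value for the overlap. Without Luciferase sgRNA replicate 3 the counts were 13 higher, of which 7 were among the 8, and the same 6 lower. The number higher in both was 2 without ETV1 sgRNA replicate 1, 4 without ETV1 sgRNA replicate 3, 3 without Luciferase sgRNA replicate 1 or 2, 4 without HAND1 sgRNA replicate 1 or 2, and 5 without HAND1 sgRNA replicate 3.

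Across the 11348 genes, which are not independent replicates, the log2 fold changes of both comparisons had a Pearson r of 0.497 and a Spearman rho of 0.512, against 0.497 (0.410 to 0.586) and 0.460 (0.435 to 0.478) in the simulations, which share the same controls. The covariance was 0.0172 against a simulated 0.00944 (0.00781 to 0.0124), a difference of 0.00780, and 69.9% of genes had the same sign against 66.6%. Leaving out Luciferase sgRNA replicate 3 gave a rho of 0.537, a covariance of 0.0192 and 70.3% of genes with the same sign. With 3 control libraries no split leaves 2 in each part, so part of the excess of shared calls over independent lists may come from the shared controls. The control sgRNA has no counterpart in human cells, while both other sgRNAs have a target there. Changes shared by both thus cannot be told apart from a response to any sgRNA with a target in the cells.

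**Figure D4:**
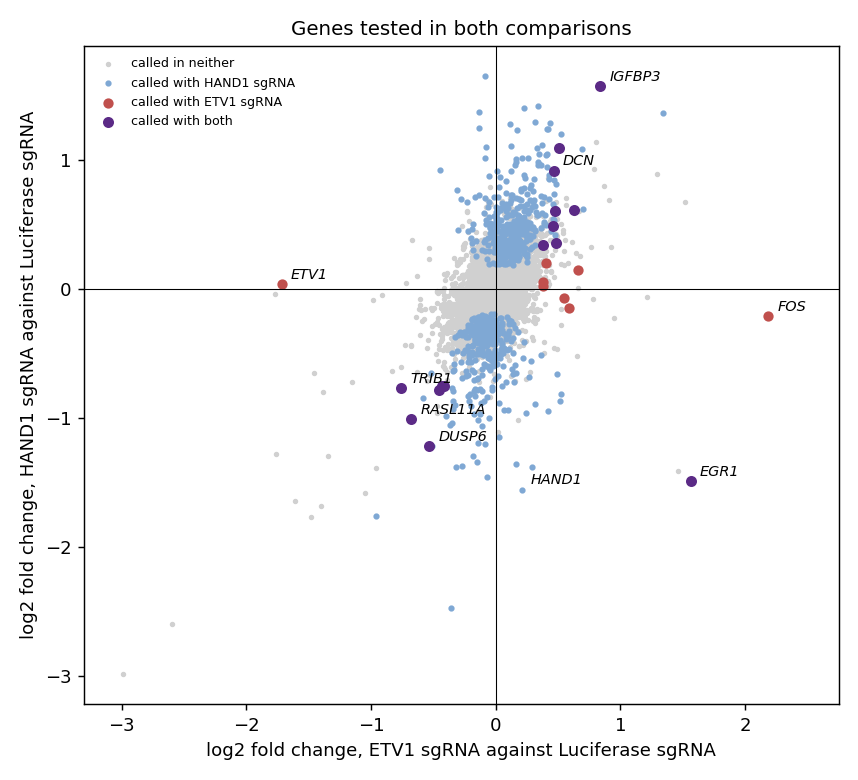
Log2 fold change of FPKM + 1 with HAND1 sgRNA against that with ETV1 sgRNA, both against Luciferase sgRNA, for the 11348 genes tested (grey: called in neither comparison). EGR1 was called higher with ETV1 sgRNA and lower with HAND1 sgRNA, while DCN and IGFBP3 were called higher and DUSP6, RASL11A and TRIB1 lower with both.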

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

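The fit with the length trend removed and the estimated correlation without Luciferase sgRNA replicate 3 were chosen after seeing the data. ETV1 and HAND1 kept their fall with their own sgRNA under every alternative, between −1.75 and −1.67 and between −1.60 and −1.52 (log2) with a library left out. The count for ETV1 sgRNA against Luciferase sgRNA, 23, was 45 with library weights and 36 with the length trend removed, both holding all 23. It was 14 with only the 2 groups in the fit (fewer samples), 3 with the 2-fold threshold and 11 to 28 with a library left out. For HAND1 sgRNA against Luciferase sgRNA, 749 became 1312 with library weights, 48 with the 2-fold threshold and 433 to 729 with a library left out. For HAND1 sgRNA against ETV1 sgRNA, 460 became 34 with the 2-fold threshold and 271 to 592 with a library left out. Of the genes changed with both sgRNAs, the number higher, 8, became 5 without the intensity trend, 19 with library weights, 15 with the length trend removed, 4 with only the 2 groups in the fit, 0 with the 2-fold threshold and 2 to 13 with a library left out. The number lower, 6, became 0 with the 2-fold threshold and 4 to 6 with a library left out. Except for the fits with fewer samples or a stricter threshold, the cause was not tested.

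Among called lists, the medians that changed sign were those of ribosomal proteins (0.0647, adjusted p = 0.0378) and oxidative phosphorylation genes (0.0300, adjusted p = 0.515) with ETV1 sgRNA without Luciferase sgRNA replicate 3. With the estimated correlation and without that library they were again 0.0647 and 0.0300 (adjusted p = 0.877 and 0.909). Without Luciferase sgRNA replicate 1 they were −0.198 and −0.183. The ribosomal protein median with ETV1 sgRNA was also above 0 with library weights (0.00154, adjusted p = 0.825). Of 109 called named genes 78 kept their call under every alternative and 31 lost it under at least 1. Of 25 list calls 0 were kept under every alternative. The estimated correlation ended 22 of them, also for lists with an estimate below the preset 0.01, such as HOX genes (−0.00239). Fry ended 11 and called 8 lists that camera had not. The matrix list with each sgRNA against Luciferase sgRNA, and the smooth muscle list with ETV1 sgRNA, lost their call under 1 of 24 alternatives. That was the estimated correlation without Luciferase sgRNA replicate 3, chosen after seeing the data.

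The replicate numbers are shared across groups in the labels. Same-numbered libraries deviated from their group means with correlations from −0.146 to 0.138 over 9 pairs, and 2 of 9 libraries correlated best with their own number, so the numbers were not taken to pair libraries. With the replicate number as a block the counts were 16, 632 and 364, and 5 genes were higher and 5 lower with both sgRNAs. No absolute depth is known, so how far depth limits the calls of low genes could not be measured.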

Other observations

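The lists of immediate early and of guidance genes, the fits with the length trend removed, the counts of splits and the tests that weigh the 3 patterns below were chosen after the results were seen, as were ETV4, ETV5, JUNB, IER2 and the guidance genes named here. The bounds for an effect of either sgRNA and the tests of ERK output, of gene length and of the shared controls were revised after a first result. The fits that leave out a library had been planned.

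Immediate early genes, transcription factors and regulators induced within minutes of a stimulus, were listed after EGR1 and FOS were seen, and the list holds both, so it is no test of the group. In limma 3 of its 19 measured members rose and 0 fell with ETV1 sgRNA, and 3 rose and 3 fell with HAND1 sgRNA. Between the sgRNAs 5 were lower and 1 higher with HAND1 sgRNA, and 13 were not called. JUNB was at 28.2 FPKM (mean, n = 3) with ETV1 sgRNA, 19.7 with Luciferase sgRNA and 12.2 with HAND1 sgRNA. IER2 was at 111, 77.6 and 43.5 FPKM in the same order. Both fell with HAND1 sgRNA (log2 −0.65 and −0.81, limma adjusted p = 0.00188 and 0.00181) and were not called with ETV1 sgRNA (0.49 and 0.52, adjusted p = 0.0825 and 0.180). ETV4 and ETV5, the ETS factors closest to ETV1, were at −0.05 and −0.04 with ETV1 sgRNA (adjusted p = 0.824 and 0.892) and fell by 0.27 and 0.30 with HAND1 sgRNA (adjusted p = 0.00659 and 0.00540).

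Among 37 measured semaphorin, ephrin and netrin guidance genes 4 rose and 4 fell in limma with HAND1 sgRNA. The list as a whole had a camera p of 0.243. EPHB1 (log2 1.66), NTN4 (0.68), SLIT2 (0.58) and EFNB2 (0.52) rose, and SEMA7A (−1.04), NRP2 (−0.93), UNC5B (−0.48) and NRP1 (−0.42) fell. With ETV1 sgRNA limma called 0 of the 37, and the list had a camera p of 0.342.

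The 6 libraries of each comparison split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 23, 749 and 460 genes, the largest count in 1 of the 10 splits of each, and the highest of the other splits was 0 in each. Each other split mixes libraries of both groups, so differences between the groups widen its spread. A low count there is thus no support for the calls.

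Ribosomal protein and oxidative phosphorylation genes were lower as lists with both sgRNAs, which made 4 list calls at the preset correlation, all lost with an estimated correlation (adjusted p = 0.826 for both lists with ETV1 sgRNA and 0.673 for both with HAND1 sgRNA). Of the 4, 0 were kept without Luciferase sgRNA replicate 3, 4 without replicate 1 and 4 without replicate 2, as that library as the source would need. Both calls with ETV1 sgRNA were also lost without ETV1 sgRNA replicate 2 (adjusted p = 0.211 and 0.1) and with library weights (0.825 and 0.439), and both ribosomal protein calls with quantile normalization (0.418 and 0.0566). Gene length bias as the whole cause cannot be told apart from the rest, because 3 of the 4 calls were kept at the preset correlation with the length trend removed, while with an estimated correlation no call was there to keep, either before or after the removal (lowest adjusted p after it 0.389), so that p decides nothing. Without Luciferase sgRNA replicate 3 the ribosomal protein and oxidative phosphorylation medians were 0.0647 and 0.0300 with ETV1 sgRNA. A lowering by ETV1 sgRNA would need both below 0. With HAND1 sgRNA they were −0.0107 and −0.0397. With an estimated correlation, still without that library, each list had an adjusted p of at least 0.872. The medians with ETV1 sgRNA thus showed no lowering without that library, but with the estimate neither list was called in either direction. An effect of either sgRNA therefore stays open and cannot be told apart from that library.

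EGR1 and FOS rose with ETV1 sgRNA, and of the other 17 MAPK output genes SPRY1 rose (log2 0.40) while DUSP6 (−0.53) and SPRY4 (−0.41) fell, SPRY4 losing its call with quantile normalization (adjusted p = 0.166) and with only the 2 groups in the fit (0.0545). No single library accounts for the rise, since the highest adjusted p of both genes with any of the 6 libraries left out was 8.59e-04. Whether ERK output rose as a whole cannot be told, because those 17 genes went both ways, with a median of −0.04, 7 above 0 and a camera p of 0.486 with an estimated correlation. Handling at harvest cannot be told apart from an effect of the sgRNA, because the other 17 immediate early genes, with a median of −0.04 and 8 above 0, had a camera p of 0.266 with an estimated correlation. A change in the induction of EGR1 and FOS with loss of ETV1 stays open and was not tested.

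Extracellular matrix genes were higher as a list with both sgRNAs. Both calls held with an estimated correlation (adjusted p = 0.0145 with ETV1 sgRNA and 0.00863 with HAND1 sgRNA) and, at the preset correlation, without any 1 library. They were lost with the estimate and without Luciferase sgRNA replicate 3 together (0.116 and 0.0622). The medians were then 0.160 and 0.393, against 0.142 and 0.348 with all 9 libraries. No other library was left out with the estimate, so the loss is not shown to be particular to replicate 3. With the length trend removed the higher of the 2 adjusted p was 2.46e-09, and 0.0405 with an estimated correlation, which argues against gene length bias. With only the 6 libraries of HAND1 sgRNA and ETV1 sgRNA in the fit, the list was higher with HAND1 sgRNA in the rotation test (adjusted p = 0.00374), which argues against the shared controls as the whole cause of the part with HAND1 sgRNA, but it was not called by camera with an estimated correlation (adjusted p = 0.267, and 0.0937 with all 9 libraries). For the part with ETV1 sgRNA they cannot be told apart from an effect of the sgRNA: the highest adjusted p without each control library was 5.02e-07 at the preset correlation, but 3 libraries cannot be split into sets of 2. An effect of either sgRNA on matrix transcripts stays open.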
